A study of Caenorhabditis elegans with 9 samples.

How the data were processed

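The data are peak lists from ATAC-seq of C. elegans embryos whose eggshells were digested with chitinase before nuclei were taken for transposition. Of 9 samples, 8 are ATAC-seq libraries in 4 groups of 2, and 1 is a wild-type input sample that was not analysed here. Per the submitters' processing notes, Trim Galore 0.4.4, BWA 0.7.17 and MACS2 2.1.1 were used with genome build ce11. The notes give no role, order or option for them, so how adapters, duplicates and the transposase offset were treated, and whether the input served as control, is not stated. Peaks were called per sample and replicates were not pooled. The lists have the peak caller's layout, with no q above 0.0495 and no peak shorter than 150 bp.

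Each peak carries values computed by the authors within its own library. The score in the deposited lists is 10 times the −log10 q, cut to a whole number. The fold in the deposited lists is the ratio of the pileup at the summit to the caller's local background. The −log10 p-value and −log10 q-value are the authors' own per-peak values, and a second deposited list per library gives summit positions with the −log10 q. The −log10 p and −log10 q grow with depth, so regions were ranked by −log10 q only within a list. An exception is the alternative of −log10 q of at least 5, which is 1 cutoff for all lists. It kept 61.6% and 63.7% of the double-mutant peaks, against 93.4% and 95.6% in let-418 at 26 °C. Medians of the fold, and medians and shares of −log10 q, are given per library to describe the lists. A difference between libraries in −log10 q may come from depth. The number of reads per library is unknown, and the peaks per list are the only sign of depth.

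Peaks on the 6 nuclear chromosomes from all 8 lists were merged into regions wherever they overlapped by at least 1 bp. A library held a region where it had a peak overlapping it. In each of 4 comparisons a region was gained where both libraries of the first group and neither of the second held it, and lost in the reverse case. Each of the 4 mixed pairs, 1 library from either group against the rest, gave the counts that the spread between libraries produces. Regions were classed as gene end, gene interior or beyond genes with a gene table of assembly WBcel235, which is the assembly called ce11. Before the data were examined, the design set a promoter window upstream of transcript starts and separate exon and intron classes. The gene table has no strand, transcript starts or exons, so the window was placed at either gene end, 1000 bp outside to 200 bp inside, and the exon and intron classes were not run. Chromosome arms are the outer 66.7% of each chromosome, with extents taken from the highest position in the gene table or peak lists.

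Gained and lost regions were compared with the regions held by all 4 libraries, and apart from that with the regions held by 1 library of either group, by two-sided Fisher's exact tests across regions, adjusted by Benjamini-Hochberg over 40 tests each. Gene lists were tested by two-sided Fisher's exact tests across genes, with the genes that had a gene-end region in at least 2 of the 4 libraries as background, adjusted over 200 tests (25 lists, 4 comparisons, both directions), at an adjusted p threshold of 0.05. The 25 lists, fixed before the data were examined, named 1751 members, of which 1743 matched a gene. They were germ granule and maternal germline, meiosis, sperm, small RNA pathway, NuRD and MEC, NURF, ISWI and SWI/SNF, synMuv and DREAM, histone methylation, heat shock and chaperone, endoderm and intestine, muscle, pharynx, epidermis and cuticle, neuron, Hox and body-axis, Wnt and Notch, apoptosis, cell cycle, dosage compensation and sex determination, ribosomal protein, cuticle collagen, nuclear hormone receptor, ceh homeobox, innate immunity and detoxification, and histone genes. Of the 200 tests 9 passed.

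The genes named in the text follow a rule fixed beforehand. For each comparison and direction it takes the 10 gene-end regions at named genes with the highest rank, plus up to 15 list members with a changed region per comparison, plus let-418 and nurf-1. The rank is the lower of the within-list percentiles of −log10 q in the 2 libraries that held the region. Further list members named beside a count, such as the collagen genes and the sperm genes, were chosen after their values were seen.

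Alternatives fixed beforehand were a stricter peak threshold (−log10 q of at least 5), lists shortened to an equal length of 8822 peaks, a library holding a region only where its peaks cover 50% of it, regions built from summits within 150 bp, peaks within 200 bp merged, an absent group that may hold the peak in 1 library, a gene-end window of 500 bp outside and 100 bp inside, and each library left out in turn. Leaving out each library for the gene-end shares and for the lists that passed was added after seeing the data, because wild-type replicate 1 and the double-mutant libraries stood apart. Testing the lists over distinct gene-end regions in place of genes was also added after seeing the data, because neighbouring genes share regions.

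The region step was tested on simulated data of 2 libraries against 2, and the list test apart from it on simulated genes. With 6000 sites and 200 sites present in only the first group, and as many in only the second, each seen with a chance of 90.0% per library, 158 gained (79.0%) and 161 lost (80.5%) were called, where 81.0% was the expected share. Of the sites present in both groups, 100 were called gained or lost, and mixed pairs gave 41 to 48. The simulated sites were seen more evenly than those of the real lists. There, replicates shared 0.317 to 0.646 of their regions (Jaccard index) and mixed pairs gave 52 to 652. The simulation therefore does not give the share of missed or false calls in the real data. For the list test, genes were drawn independently with a set chance of change and were not taken from these sites. A list given a higher chance had an odds ratio of 6.46 (p = 3.00e-12, Fisher's exact test), and 1 of 500 lists without an effect was called. No simulated genes shared a region, so the step from regions to genes was not tested. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals are 95% Wilson intervals and cover counting error only.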

Results

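Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts adapters into open DNA, in nuclei of C. elegans embryos. The study asked how a point mutation in let-418, which encodes the Mi-2 chromatin remodelling ATPase of the NuRD and MEC complexes, changes accessible chromatin, and whether a stop mutation in nurf-1, which encodes the large subunit of the NURF remodelling complex, alters that profile. The series concerns sterility of the let-418 mutant and its rescue. There were 4 groups of 2 libraries each: wild type at 26 °C, let-418(L781F) at 20 °C, let-418(L781F) at 26 °C, and let-418(L781F) nurf-1(Q1336stop) at 26 °C, called the double mutant here. No wild type at 20 °C was among the samples, so temperature was compared in the let-418 mutant alone. The number of reads behind each library is unknown. Peaks were called per sample by the authors, 89145 in all, and all comparisons rest on whether a library's list held a peak in a region.

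The wild-type lists held 13779 and 9772 peaks, the let-418 20 °C lists 9579 and 8873, the let-418 26 °C lists 8823 and 10884, and the double-mutant lists 12006 and 15429. The double-mutant lists stood apart in the −log10 q of their peaks, a value that also grows with depth. The authors' median −log10 q per peak was 6.35 and 5.97 in the double mutant, 16.6 and 16.3 in wild type, 12.8 and 16 in let-418 at 20 °C, and 18.7 and 24.4 in let-418 at 26 °C. Their median fold over the local background was also lowest in the double mutant (2.88 and 2.99). It was 4.03 and 4.06 in wild type, 3.44 and 3.76 in let-418 at 20 °C, and 4.85 and 4.19 in let-418 at 26 °C. Peak summits lay within the gene-end window (1000 bp outside to 200 bp inside either end of a protein-coding gene) in 33.7% and 34.5% of double-mutant peaks, against 45.6% and 45.4% in let-418 at 26 °C, 42% and 42.7% in let-418 at 20 °C, and 38.5% and 40.7% in wild type. These windows cover 36.2% of the genome, gene interiors 44%. Merging overlapping peaks of the 8 lists gave 30272 regions on the 6 nuclear chromosomes, of which 3091 were held by all 8 libraries and 15037 by 1 library alone. Wild-type replicate 1 and the double-mutant libraries contributed most of the latter, with 3992, 3501 and 5132 such regions. The regions held by all 8 libraries lay at gene ends in 52.8% of cases and in gene interiors in 22.7%.

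**Figure D1:**
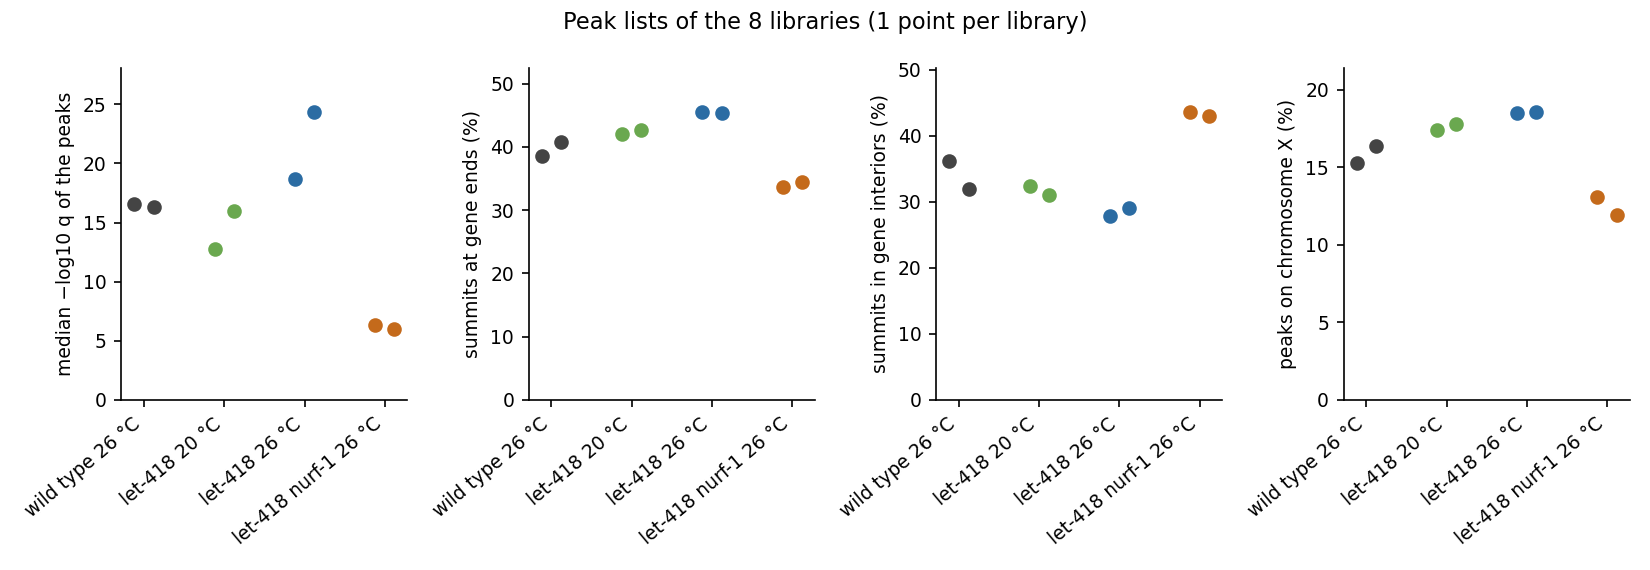
Median −log10 q of the peaks, percent of summits at gene ends, percent of summits in gene interiors and percent of peaks on chromosome X (vertical axes), with 1 point per library for the 4 groups (horizontal axis). The double-mutant points lie lowest in strength (6.35 and 5.97), gene-end share (33.7% and 34.5%) and X share (13.1% and 11.9%), and highest in gene-interior share (43.7% and 43%).

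The mutated genes themselves were examined first. At let-418, on chromosome V from 5826833 to 5832831 in build ce11, a region at 5826194 to 5826490 was held by both libraries of wild type and of let-418 at each temperature and by 1 double-mutant library. A neighbouring let-418 region at 5825596 to 5825980 was held by 1 wild-type, 1 let-418 20 °C, 2 let-418 26 °C and 0 double-mutant libraries. At nurf-1, on chromosome II from 14390713 to 14407911, a region at 14390100 to 14390316 was held by both wild-type and both let-418 26 °C libraries and by 0 of the let-418 20 °C and double-mutant libraries. The nurf-1 region at its other end, 14407577 to 14407866, was held by 1 wild-type and 1 let-418 26 °C library. Regions at gene ends do not check a label that names a point or stop mutation, and peak lists carry no sequence.

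Libraries of 1 group were not always more alike than libraries of different groups. The share of regions held in common (Jaccard index) was 0.646 between the let-418 26 °C replicates and 0.605 between the let-418 20 °C replicates, with 0.569 to 0.590 between these groups. It was 0.479 between the wild-type replicates, within the range of 0.349 to 0.522 between wild type and let-418 at 26 °C. The double-mutant replicates shared 0.317, within the range of 0.305 to 0.328 between double mutant and let-418 at 26 °C. That is below the 0.322 to 0.354 between double mutant and let-418 at 20 °C. A region was therefore called gained only where both libraries of the first group and neither library of the second held a peak, and lost in the reverse case, and each count was set beside those of the 4 mixed pairs, each made of 1 library of either group. With 2 libraries against 2, no exact test of a region can give a p below 0.333, and the Fisher tests run across regions or genes, which are not replicates. The labels do not say whether replicates were separate cultures, so the spread between libraries may be technical only. Intervals are 95% Wilson intervals and cover counting error only.

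In let-418 embryos at 26 °C, accessible regions were lost mostly away from gene ends, while the gained regions lay at gene ends and in gene interiors about as often as regions that divide the same libraries across groups, and more often on chromosome arms. Against wild type at 26 °C, 1079 regions were gained and 1891 lost, with 52 to 423 in the mixed pairs and 4736 regions held by all 4 libraries. Of the lost regions, 31.4% lay at gene ends (interval 29.3 to 33.5) and 45.8% in gene interiors (43.6 to 48.0), against 56.2% and 21.1% of the regions held by all 4 (Fisher's exact test, adjusted p = 9.10e-75 and 3.22e-85). By base, gene ends make up 36.2% of the genome and gene interiors 44%. The lost regions were thus spread more like the genome than like the regions held by all 4, which was not tested. Chromosome X held 9.84% of the lost regions against 19.1% (adjusted exact p = 4.35e-21). Of the gained regions, 47.5% lay at gene ends (44.5 to 50.4, adjusted exact p = 4.00e-07), 29.3% in gene interiors (adjusted p = 2.78e-08) and 19.2% on X (adjusted p = 0.966). Against the 968 regions held by 1 library of either group, the gained regions did not differ at gene ends (49% of the 968, adjusted exact p = 0.596) or in gene interiors (28.4%, adjusted p = 0.795), while the lost regions did (adjusted p = 3.96e-19 and 6.69e-19). Chromosome arms, the outer 66.7% of each chromosome, held 76.7% of the gained and 77.9% of the lost regions, against 69.1% of those held by all 4 (adjusted exact p = 8.57e-07 and 7.38e-13) and 65.5% of the 968 (adjusted p = 7.27e-08 and 6.18e-12). In the let-418 26 °C lists the summits at gene ends were also more frequent (45.6% and 45.4%) than in the wild-type lists (38.5% and 40.7%). Leaving out a library raised the gained count to 2966 without let-418 26 °C replicate 1, 1689 without its replicate 2, 1664 without wild-type replicate 1 and 2035 without wild-type replicate 2. The lost count rose to 6774 without wild-type replicate 2. Without let-418 26 °C replicate 1 the gained regions outnumbered the lost ones (2966 against 2090). Where the absent group may hold the peak in 1 library, 2620 were gained and 2459 lost, and gained regions made up 51.6% of those changed rather than 36.3%.

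Among the strongest gained gene-end regions of let-418 at 26 °C was tmem-231, which encodes a protein of the ciliary transition zone. Its region on chromosome IV, 8428476 to 8428952, ranked at percentile 87.3 or higher in both let-418 26 °C lists and was absent from both wild-type lists. The riok-1 region, at a RIO kinase gene (I, 3096202 to 3096464), reached percentile 75.3. Other gained regions lay at dnj-2, which encodes a DnaJ-domain protein (percentile 69.1), the cadherin gene cdh-9 (69.1), the RNA polymerase subunit gene rpb-6 (64), nspg-4 (62.9), the splicing factor gene uaf-2 (62.4), the nuclear RNAi gene nrde-2 (61.6), the ABC transporter gene mrp-2 (60.6) and the mRNA decapping gene dcap-1 (59.9). Of these 10 regions, all but that of nrde-2 were also held by both let-418 20 °C libraries. The strongest lost region lay at the homeobox gene ceh-76 (V, 7993244 to 7993571, percentile 90.6 in the wild-type lists). It was followed by mihp-1 (88.3), rom-3 (86), acbp-4 (78.8), the major sperm protein gene msp-113 (77.4), the chemoreceptor-family gene srxa-8 (75.3), droe-4 (73.3), cya-2 (71.9), the glucuronosyltransferase gene ugt-24 (71.9) and haf-6 (70.1).

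Grouped by the gene lists fixed beforehand, 712 of 6310 protein-coding genes with a gene-end region gained one in let-418 at 26 °C against wild type and 764 lost one. Of 11 germ granule and maternal germline genes, car-1, mex-1 and ifet-1 gained a region and glh-1, which encodes a Vasa-related helicase of germ granules, lost one at I, 6854305 to 6854687 (percentile 65.7). Neither share differed from that of other genes (27.3% against 11.3%, adjusted exact p = 0.698, and 9.09% against 12.1%, adjusted p = 1.00). Of 8 sperm genes 3 gained a region (spe-6, spe-44 and fer-1, adjusted exact p = 0.468). Of 10 small RNA pathway genes nrde-2 gained one (adjusted exact p = 1.00), and of 28 heat shock and chaperone genes 5 gained one (cct-6, hsp-90, cct-8, sip-1 and hsp-1, adjusted p = 0.911). The engulfment receptor gene ced-1 lost a region (I, 11851163 to 11851487, percentile 53.3), as 1 of 7 apoptosis genes (adjusted exact p = 1.00). Of 100 innate immunity and detoxification genes 21 lost a region, among them ugt-24, spp-24, ugt-20, clec-118 and spp-17 (21% against 12%, adjusted exact p = 0.187), and 15 gained one, among them clec-103 (adjusted p = 0.911). Of 36 ceh homeobox genes 6 gained a region (adjusted exact p = 0.933) and 2 lost one (adjusted p = 0.937). Of 92 nuclear hormone receptor genes 12 gained one, among them nhr-12 and nhr-41 (adjusted exact p = 1.00), and 7 lost one, among them nhr-275 (adjusted p = 0.911). Cuticle collagen genes lost a region in 9 of 29 cases (31% against 12%, adjusted exact p = 0.0940).

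By the rule of both libraries against neither, histone and ribosomal protein genes were absent from the losses in this comparison, which depends on the settings for the ribosomal protein genes and on counting by gene for the histone genes. Of 69 histone genes 0 lost a region, against 12.2% of other genes (adjusted exact p = 0.00870, range 1.44e-04 to 0.0469 over 5 alternatives), though histone genes are multi-copy and their peaks are uncertain because reads from near-identical copies cannot be assigned to 1 gene. Neighbouring histone genes also share regions, and counted over distinct regions the result did not pass (0 of 34 against 11.3%, adjusted exact p = 0.460). Without wild-type replicate 2, 8 of the 69 lost one, against 38.1% of other genes (adjusted exact p = 1.38e-04). Of 63 ribosomal protein genes with a region, 0 lost one against 12.2% (adjusted exact p = 0.0175), and 6 gained one, among them rpl-31 (adjusted p = 1.00). The ribosomal protein result did not pass with equal list lengths (adjusted exact p = 0.204), with regions counted as held only where peaks cover 50% of them (0.240), with the narrower gene-end window (0.0594), where the absent group may hold the peak in 1 library (0.454) or without let-418 26 °C replicate 2 (5 of 62, 0.841), in a range of 0.0264 to 0.454 over the 5 alternatives. Over distinct regions it passed (0 of 88 against 11.4%, adjusted exact p = 0.00478). Without wild-type replicate 1 it was 2 of 62 against 16.3% (odds ratio 0.171) and without wild-type replicate 2 it was 11 of 63 against 38% (odds ratio 0.345).

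**Figure D2:**
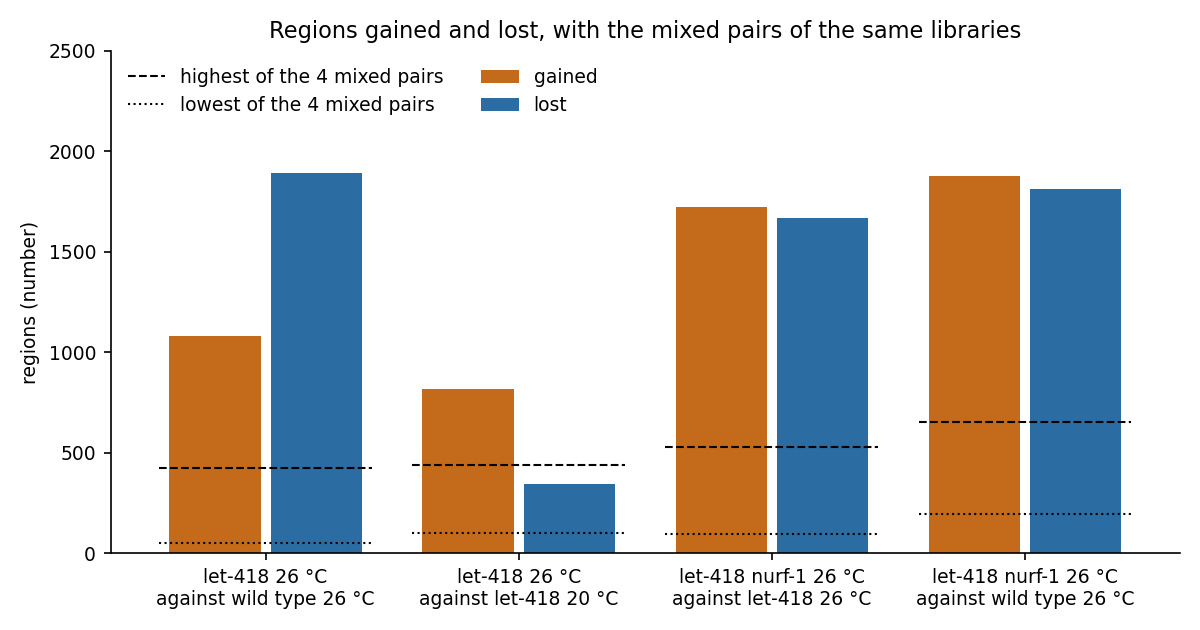
Number of regions gained and lost (vertical axis) in each of the 4 comparisons (horizontal axis), with dashed and dotted lines at the highest and lowest count among the 4 mixed pairs of the same libraries. The bars lie above the highest mixed pair except for the 345 regions lost in let-418 at 26 °C against 20 °C, where the highest mixed pair gave 440.

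Raising the temperature of the let-418 mutant from 20 °C to 26 °C went with more gained than lost regions in the lists as given, an order that turned without let-418 20 °C replicate 2 (1301 gained and 1679 lost). At 26 °C 818 regions were gained and 345 lost, with 5525 held by all 4 libraries. The gained count exceeded the mixed pairs (99 to 440), and the lost count did not. With equal list lengths both did (693 gained and 482 lost, highest mixed pair 247). Gained regions lay at gene ends in 57.7% of cases (54.3 to 61.0) against 54.2% of the regions held by all 4 (Fisher's exact test, adjusted p = 0.0726), which passed with equal list lengths (60.2%) and with the narrower gene-end window (46.8%). They lay less often on chromosome arms (64.9% against 71.8%, adjusted exact p = 9.21e-05). Lost regions lay at gene ends in 39.4% (34.4 to 44.7, adjusted exact p = 2.20e-07), in gene interiors in 39.1% (adjusted p = 9.79e-11) and on arms in 83.5% (adjusted p = 1.89e-06). Against the 1035 regions held by 1 library of either group, the lost regions did not differ in gene interiors (34% of the 1035, adjusted exact p = 0.135) and differed at gene ends (46.9%, adjusted p = 0.0281) and on arms (71.8%, adjusted p = 2.48e-05), and the gained regions lay more often at gene ends (adjusted p = 7.95e-06). The 26 °C lists had the higher median −log10 q (18.7 and 24.4 against 12.8 and 16). Gained regions made up 70.3% of those changed, 59.0% with equal list lengths, and the gained count was 1831 where the absent group may hold the peak in 1 library. It was 2477 without let-418 26 °C replicate 1, 1478 without its replicate 2, 1348 without let-418 20 °C replicate 1 and 1301 without its replicate 2. The lost count was 225 with only peaks of −log10 q of at least 5, 1024 where the absent group may hold the peak in 1 library, 925 without let-418 26 °C replicate 2, 1233 without let-418 20 °C replicate 1 and 1679 without its replicate 2.

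The strongest region gained at 26 °C lay at tom-1, which encodes tomosyn, a regulator of synaptic vesicle release (I, 5545620 to 5545880, percentile 68.5). It was followed by gbh-1 (65.0), the fatty acid elongase gene elo-2 (65.0), the lipoic acid synthase gene lias-1 (64), lsm-6 (61.1), the translation initiation factor gene inf-1 (60.1), mif-1 (60.1), a region shared by fau-1 and rpl-39 (V, 7776232 to 7776463, 59.1), bath-36 (59.0) and hsp-90, which encodes the HSP90 chaperone (V, 14685634 to 14685913, 58.3). The hsp-90 region was held by 1 wild-type, 0 let-418 20 °C, 2 let-418 26 °C and 0 double-mutant libraries. Regions lost at 26 °C were of lower rank and lay at nspe-8 (43.1), the cytochrome P450 gene cyp-25A6 (43.1), the glutamate-gated chloride channel gene glc-4 (42), mek-5 (41.5), ttm-5 (39.9), spi-2 (39.9), rac-2 (34), blos-1 (29.8), scd-1 (29.8) and idpa-1 (29.8).

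For temperature only the histone genes passed, and only when counted by gene. Of these 0 of 69 gained a region against 12.4% of other genes (adjusted exact p = 0.00870, range 1.88e-06 to 0.0408 over 5 alternatives, multi-copy), but over the distinct regions that they share it was 0 of 37 against 9.70%, which did not pass (adjusted p = 0.460). In all, 711 of 5803 genes gained a gene-end region and 182 lost one. Of 15 meiosis genes 5 gained a region (33.3% against 12.2%, adjusted exact p = 0.317), as did 3 of 8 sperm genes (adjusted p = 0.468), 2 of 10 germ granule genes (adjusted p = 0.937) and 3 of 26 heat shock and chaperone genes (11.5%, against 708 of 5777 other genes, adjusted p = 1.00). Of 26 epidermis and cuticle genes 7 gained a region, among them dpy-10 (26.9% against 12.2%, adjusted exact p = 0.344), and of 82 nuclear hormone receptor genes 17 did, among them nhr-50, nhr-241 and nhr-228 (20.7% against 12.1%, adjusted p = 0.317). Ribosomal protein genes gained a region in 12 of 62 cases, among them rpl-39, rpl-37A and rpl-5 (19.4% against 12.2%, adjusted exact p = 0.696). The rpl-5 region is shared with col-38 (II, 8569400 to 8569616). Of 15 synMuv and DREAM genes 3 gained a region, among them the E2F gene efl-1 (adjusted exact p = 0.968), and of 9 NURF, ISWI and SWI/SNF genes nurf-1 did (adjusted p = 1.00).

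In the double mutant, gene-end regions were lost and regions in gene interiors and on chromosome arms were gained, relative to let-418 at 26 °C. There were 1722 regions gained and 1670 lost, with 93 to 526 in the mixed pairs and 3875 held by all 4 libraries. Lost regions lay at gene ends in 62.7% of cases (60.3 to 65.0) against 50.4% of the regions held by all 4 (Fisher's exact test, adjusted p = 7.96e-17) and on X in 22.8% against 17.9% (adjusted p = 5.04e-05). Gained regions lay in gene interiors in 46.7% (44.4 to 49.1) against 973 of the 3875 (adjusted exact p = 3.03e-55), at gene ends in 35.4% (adjusted p = 5.85e-25), on arms in 88.4% against 71.4% (adjusted p = 5.51e-47) and on X in 6.10% (adjusted p = 1.49e-34). Against the 1143 regions held by 1 library of either group, of which 37.2% lay in gene interiors and 40.4% at gene ends, gained regions stayed above in gene interiors (adjusted exact p = 1.16e-06) and lost regions at gene ends (adjusted p = 5.19e-30). The double-mutant lists as a whole moved the same way, with fewer peaks of high −log10 q (61.6% and 63.7% of peaks at −log10 q of at least 5, against 93.4% and 95.6%) and with 43.7% and 43% of summits in gene interiors against 27.8% and 29%. Gained regions made up 50.8% of those changed, but 24.1% among peaks of −log10 q of at least 5 (678 gained and 2137 lost), so that losses outnumbered gains, and 29.6% with equal list lengths (840 and 1997). The gained count was 8261 without double-mutant replicate 1 and 5780 without its replicate 2, and the lost count was 3481 where the absent group may hold the peak in 1 library, 3310 without let-418 26 °C replicate 1 and 2856 without double-mutant replicate 2.

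The strongest regions that the double mutant lacked were held by all 6 libraries of the other groups. They lay at fbxb-45 (II, 1043934 to 1044236, percentile 84.6), at jmjc-1, a JmjC-domain gene (I, 3636355 to 3636837, 84.4), at fah-1, which encodes fumarylacetoacetate hydrolase (84.4), the prefoldin gene pfd-1 (84), the autophagy gene atg-9 (83.4), gex-2 (82.9), the proton pump genes vha-8 (82.9) and vha-3 (80.6), the Rab GTPase gene rab-6.2 (82.6) and the nucleoporin gene npp-27 (80.3). Gained regions lay at nssp-50 (V, 3053195 to 3054123, 82.5), pqn-91 (79.6), set-29 (78.1), the glutathione transferase gene gst-25 (78.1), the chemoreceptor-family genes srj-19 (77.6) and srw-97 (74.2), the gustatory receptor-like gene gur-4 (76), semo-1 (76), the F-box gene fbxa-36 (74.5) and the lectin gene clec-145 (74.2). Of these 10 gained regions, those of srj-19 and fbxa-36 were held by no library outside the double mutant.

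Ribosomal protein genes stood out among the losses. Of 60 ribosomal protein genes with a gene-end region, 36 lost one in the double mutant against let-418 at 26 °C (60%, against 1555 of 6142 other genes, odds ratio 4.42, adjusted p = 3.37e-06 by Fisher's exact test, range 3.23e-07 to 0.0292 over 5 alternatives). Over distinct regions it was 36 of 93 against 19.3% (odds ratio 2.64, adjusted exact p = 0.00328). The strongest lay at rps-20 (I, 14469224 to 14469454, percentile 77.8), at rpl-12 in a region shared with the DREAM gene lin-54 (IV, 13240505 to 13240805, 77.8), and at rps-25 (77.5), rps-29 (77.2), rpl-29 (73.6), rpl-8 (72.0) and rpl-7 (71.1). Of the 78 ribosomal protein genes, 50% and 56.4% had a gene-end region in the double-mutant libraries, 79.5% and 83.3% in let-418 at 26 °C, 59.0% and 67.9% in let-418 at 20 °C, and 69.2% and 73.1% in wild type. Over all 19971 protein-coding genes the share was 27% and 33.5% in the double mutant, 27.4% and 31.7% in let-418 at 26 °C, and at most 33.9% in any library. In the same list 5 genes gained a region (adjusted exact p = 0.937), of which rps-20, rpl-7, rpl-4 and rpl-8 lost another one. The double-mutant lists had the lowest median −log10 q, 6.35 and 5.97.

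Cuticle collagen genes, which encode the collagens of the larval and adult cuticle, gained gene-end regions in the double mutant against let-418 at 26 °C when counted by gene. A region was gained at 12 of 34 of them (35.3% against 12.9%, odds ratio 3.69, adjusted exact p = 0.0189), and 3 lost one (adjusted p = 0.317). Against wild type 7 of 35 gained one, which did not pass (20% against 14.4%, odds ratio 1.48, adjusted exact p = 0.937). The genes were col-72 (II, 3524312 to 3524731), col-106, col-89, col-86, col-117 and col-3 at a shared region, col-62 and col-7 at another, col-120, col-105, col-71 and col-96. The result did not pass over distinct regions (10 of 38 against 11.3%, adjusted exact p = 0.281), with equal list lengths (0.0767) or with the narrower gene-end window (0.134), in a range of 4.84e-04 to 0.134 over 5 alternatives. Without double-mutant replicate 1 it was 37 of 53 (69.8% against 44.3% of other genes, odds ratio 2.90). Without its replicate 2 it was 26 of 43 (60.5% against 34.9%, odds ratio 2.86). The share of the 156 collagen genes with a gene-end region was 25.6% and 31.4% in the double-mutant libraries, 12.8% and 19.2% in let-418 at 26 °C, 16% and 13.5% in let-418 at 20 °C, and 23.7% and 16% in wild type. The double-mutant lists held more peaks than the let-418 26 °C lists (12006 and 15429 against 8823 and 10884), and more of these in gene interiors.

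Histone genes, again multi-copy and uncertain, lost a region in 3 of 69 cases against 25.9% of other genes (adjusted exact p = 4.93e-04) and gained one in 1 of 69 against 13.1% (adjusted p = 0.0368). Over the distinct regions that they share neither passed (2 of 36 lost against 19.7%, adjusted exact p = 0.460, and 1 of 36 gained against 11.5%, 0.760), and gene-end regions of the same percentile and width were lost in 5.97% of cases. The former did not pass where peaks must cover 50% of a region (adjusted exact p = 0.0895, range 2.10e-10 to 0.0895). The latter did not pass among peaks of −log10 q of at least 5 (0.281), with equal list lengths (0.413) or with 50% cover (0.0823), in a range of 0.00437 to 0.413. Losses were 7 of 69 without let-418 26 °C replicate 1 (against 39.7% of other genes, odds ratio 0.172). Gains were 5 of 69 without double-mutant replicate 1 (against 44.8%, odds ratio 0.0961). Of 16 synMuv and DREAM genes 7 lost a region, among them lin-54 and lin-15B (43.8% against 25.6%, adjusted exact p = 0.748). Of 17 histone methylation genes 6 did, among them the demethylase gene lsd-1 (adjusted exact p = 0.950), and of 27 cell cycle genes 9 did, among them cdk-2 (adjusted p = 0.937). Losses were counted at 3 of 9 NuRD and MEC genes (adjusted exact p = 1.00), 3 of 8 NURF, ISWI and SWI/SNF genes (0.968), 5 of 10 dosage compensation and sex determination genes (0.723), 8 of 27 neuron genes (1.00), 1 of 24 muscle genes (0.223), 2 of 20 Wnt and Notch pathway genes (0.701), 1 of 10 Hox and body-axis genes (1.00), 0 of 9 pharynx genes (0.701) and 0 of 4 endoderm and intestine genes (1.00). Of 98 innate immunity and detoxification genes 19 gained a region, among them gst-25 and clec-145 (19.4% against 12.9%, adjusted exact p = 0.468), and 17 lost one, among them clec-104 (0.468). Of 85 nuclear hormone receptor genes 7 gained one, among them nhr-276 (0.911). The lower −log10 q of the double-mutant lists applies to these groups too.

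**Figure D3:**
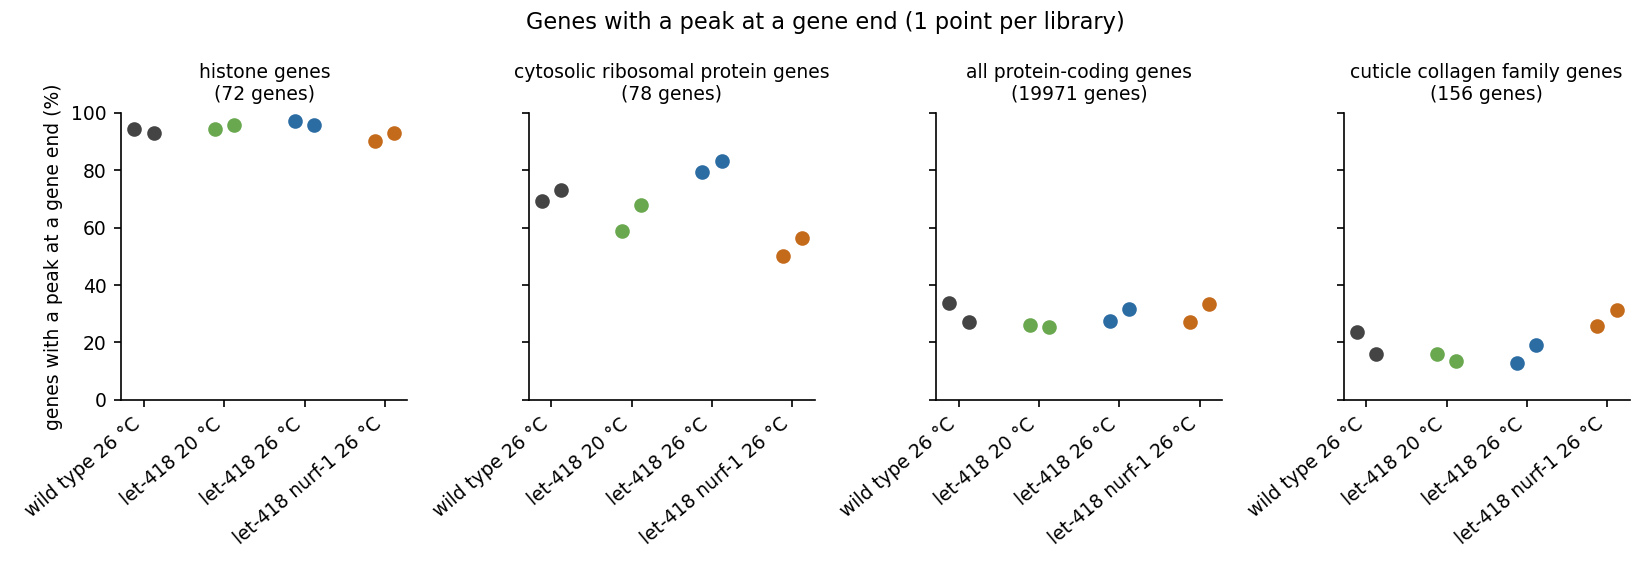
Percent of genes with a peak at a gene end (vertical axis) for histone genes, ribosomal protein genes, all protein-coding genes and cuticle collagen genes, with 1 point per library for the 4 groups (horizontal axis). Ribosomal protein genes are lowest in the double mutant (50% and 56.4%) and highest in let-418 at 26 °C (79.5% and 83.3%), collagen genes are highest in the double mutant (25.6% and 31.4%), and histone genes lie between 90.3% and 97.2% in all libraries.

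Against wild type, the double mutant also gained regions in gene interiors and on chromosome arms, and ribosomal protein genes again lost gene-end regions when counted by gene. There were 1876 regions gained and 1814 lost, with 197 to 652 in the mixed pairs and 3579 held by all 4 libraries. Gained regions lay in gene interiors in 47.8% of cases (45.6 to 50.1) against 24.8% (Fisher's exact test, adjusted p = 5.47e-64), on arms in 89.4% against 70.4% (adjusted p = 1.23e-60) and on X in 6.66% against 17.9% (adjusted p = 2.69e-32). Gene interiors make up 44% of the genome by base. Lost regions lay at gene ends in 44.9% (42.7 to 47.2) against 50.5% (adjusted exact p = 1.42e-04) and in gene interiors in 35.5% (adjusted p = 9.74e-16), and X held 14.1% of them against 17.9% (adjusted p = 3.77e-04). Against the 1498 regions held by 1 library of either group, the lost regions passed no threshold at gene ends (45.6% of the 1498, adjusted exact p = 0.806) or on X (15.1%, adjusted p = 0.519), and differed in gene interiors (31.5%, adjusted p = 0.0273). Gained regions stayed above these in gene interiors (adjusted exact p = 5.28e-21). The gene-end share of the lost regions did not pass without wild-type replicate 1 (48.2%). Gained regions made up 50.8% of those changed, but 26.7% among peaks of −log10 q of at least 5 (758 gained and 2076 lost), so that losses outnumbered gains, and 35.8% with equal list lengths (939 and 1684), with the lower −log10 q of the double-mutant lists as before. The gained count was 7899 without double-mutant replicate 1 and 6104 without its replicate 2, and the lost count was 3616 where the absent group may hold the peak in 1 library, 6411 without wild-type replicate 2 and 3227 without double-mutant replicate 2.

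Regions gained in the double mutant against wild type lay at sms-2, which encodes a sphingomyelin synthase (X, 943770 to 944390, percentile 93.4), dnj-2 (82.0), tmem-231 (81.5), rps-18 (79.0), set-29 (78.1), nspg-4 (78.1), srj-19 (77.6), fbxa-220 (76.4), irld-53 (76.4) and gur-4 (76). The regions at sms-2, dnj-2, tmem-231, rps-18 and nspg-4 were also held by both let-418 libraries at each temperature. Lost regions lay at jmjc-1 (87.8), rnf-145 (86.3), pcm-1 (85.7), atg-9 (85.4), ccd-5 (84.9), fbxb-45 (84.1), ekl-4 in the region shared with rps-20 (83.4), the nuclear transport gene ran-4 (82.8), sex-1, a nuclear receptor gene that acts in sex determination (X, 10205600 to 10205845, 82.8), and the cytochrome c oxidase gene cox-4 (81.7). These 10 regions were held by all 6 libraries of the other groups.

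Of 51 ribosomal protein genes 23 lost a gene-end region in the double mutant against wild type (45.1% against 19.8%, odds ratio 3.33, adjusted exact p = 0.00344). They included rps-20, rpl-41.1 and rpl-41.2 at a shared region (I, 4789666 to 4790184, percentile 74.9), rpl-39 (73.3), rps-29 (73.0), rpl-29 (73.0), rps-25 (71.5) and rpl-7 (70.2). The result did not pass over distinct regions (23 of 75 against 15.6%, adjusted exact p = 0.0743) or where peaks must cover 50% of a region (0.247, range 5.55e-05 to 0.247). It also did not pass without wild-type replicate 2 (33 of 56, 58.9% against 45.5%, odds ratio 1.72). Without wild-type replicate 1 it was 36 of 58 (62.1% against 30.9%, odds ratio 3.65). In the same list 9 gained a region, among them rps-18 (adjusted exact p = 1.00). Histone genes lost a region in 2 of 68 cases against 20.2% (adjusted exact p = 0.00432, multi-copy), which did not pass over distinct regions (1 of 36 against 15.9%, 0.460) or with 50% cover (0.0718, range 3.92e-09 to 0.0718). It was 7 of 68 against 45.9% without wild-type replicate 2 and 4 of 67 against 31.5% without its replicate 1. In all, 868 of 5998 genes gained a gene-end region and 1199 lost one. Of 15 synMuv and DREAM genes 5 lost one (33.3% against 20.0%, adjusted exact p = 0.911), as did ssl-1 among 3 of 8 NURF, ISWI and SWI/SNF genes (0.911) and dpy-30 among 4 of 17 histone methylation genes (1.00). Of 10 dosage compensation and sex determination genes 3 lost a region, among them sex-1 (0.968). Of 107 innate immunity and detoxification genes 23 gained one, among them clec-145 (0.468), and 23 lost one, among them ugt-24 (1.00). Of 7 sperm genes 3 gained one, among them spe-41 (0.468).

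The regions that changed in let-418 at 26 °C were then followed into the double mutant, since the series asks whether the nurf-1 mutation reverses effects of the let-418 mutation. Of the 1891 regions lost in let-418 at 26 °C against wild type, 195 were held by both double-mutant libraries (10.3%, interval 9.02 to 11.8), 656 by 1 and 1040 by neither. An example is the region at haf-6 (I, 1161104 to 1161884). Of the 1079 gained regions, 524 were held by neither double-mutant library (48.6%, 45.6 to 51.5), among them those at riok-1, rpb-6, uaf-2, mrp-2, cct-6 and clec-103. Both shares were no higher than among 968 regions that divide the same libraries across groups, 1 wild-type and 1 let-418 library each. Of these regions 18.3% were in both double-mutant libraries (Fisher's exact test of the 195, odds ratio 0.514, p = 4.86e-09) and 52.1% in neither (odds ratio 0.869, p = 0.121). In the let-418 20 °C libraries, 2.01% of the lost regions were held by both, against 21.1% of the 968, and 29.8% of the gained regions by neither, against 52%.

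The comparisons behind these overlaps share the let-418 26 °C libraries. Independent lists of these lengths would share 233 lost and 129 gained regions. In 100 simulations each region was called with a chance set by its share of the same 6 libraries, drawn independently for each library. They gave 285 to 372 and 175 to 244. The draws leave out the likeness of replicates, and the observed 195 and 524 lie below and above them, so they set no range for overlap without an effect. Among the 15 choices of 2 of the 6 libraries at 26 °C as the pair set apart, 4 gave at least 195 (highest other choice 581) and 3 at least 524 (highest other 1315). The 195 was 356 where the absent group may hold the peak in 1 library, 96 among peaks of −log10 q of at least 5, 102 with equal list lengths, where the odds ratio of 0.719 did not pass (exact p = 0.0555), 55 with 50% cover and 110 with regions built from summits. It was 387 without wild-type replicate 2, 301 without let-418 26 °C replicate 2 and 783 without double-mutant replicate 1. The 524 was 1089 where the absent group may hold the peak in 1 library, 859 without wild-type replicate 2, 1620 without let-418 26 °C replicate 1 and 936 without its replicate 2. Its odds ratio passed below 1 among peaks of −log10 q of at least 5 (0.816, exact p = 0.0329), with equal list lengths (0.748, p = 0.00395), with 50% cover (0.803, p = 0.0114) and with peaks within 200 bp merged (0.812, p = 0.0242). The lower −log10 q of the double-mutant lists applies here too.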

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

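Every library's list held 1 peak that spans the mitochondrial genome from 1 to 13794, which lies outside the nuclear regions compared in the report. It was singled out as signal in data that no comparison used. The authors' fold for this peak was 5404 and 4494 in the wild-type libraries, 2114 and 2798 in let-418 at 20 °C, 3702 and 2800 in let-418 at 26 °C, and 668 and 795 in the double mutant. The fold of this peak is measured against each library's own background and was not compared between libraries, and no explanation was tested.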

How the results depend on the processing

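Of 311 alternative values, 245 kept their direction and side of the threshold (for counts, stayed within 1.5 times), 42 counts moved further, 22 results fell short of the threshold, 2 passed it newly and 0 reversed. These labels take each count by itself. The order of gained and lost regions turned for let-418 at 26 °C against wild type (2966 and 2090 without let-418 26 °C replicate 1, 2620 and 2459 with the looser absence rule) and against 20 °C (1301 and 1679 without let-418 20 °C replicate 2). It also turned for the double mutant in both comparisons, where main counts were nearly equal. The alternatives were fixed before the data were examined, except leaving out libraries for gene-end shares and passing lists, and testing lists over distinct regions. Over regions, the histone and collagen results did not pass (adjusted exact p 0.281 to 0.760), nor did the ribosomal protein losses against wild type in the double mutant (0.0743). For the results that moved, the cause was not tested, unless named here.

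Allowing the absent group the peak in 1 library, a looser rule by construction, gave 2620 gained for let-418 at 26 °C against wild type, 1831 gained and 1024 lost against 20 °C, 3481 lost in the double mutant against let-418 and 3616 against wild type, and in the double mutant 356 of the lost regions present and 1089 of the gained regions absent. Only peaks with −log10 q of at least 5 gave 225 lost with temperature, 678 and 758 gained in the double mutant against let-418 and wild type, and 96 lost regions present there. Equal list lengths gave 840 and 939 gained in the double mutant and 102 lost regions present. With 50% cover 55 were present, and with regions from summits 110. The gene-end share of regions gained with temperature passed with equal lengths (60.2%) and the narrower window (46.8%).

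With 1 library left out, a region needs fewer libraries to be called, so counts mostly rose. For let-418 at 26 °C against wild type they were 1664 to 2966 gained and 2090 to 6774 lost; against 20 °C, 1301 to 2477 and 444 to 1679. For the double mutant against let-418 they were 1873 to 8261 gained and 2235 to 3310 lost; against wild type, 2257 to 7899 and 2203 to 6411. Lost regions present in the double mutant were 215 to 783, gained regions absent from it 666 to 1620. The gene-end share of regions lost in the double mutant against wild type was 41.2% to 48.2%, and did not pass without wild-type replicate 1.

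Groups share replicate numbers, but the labels do not say that a number marks a shared culture or batch. No paired analysis was possible because the rule of both libraries against neither gives the same count however libraries are paired and has no error term for a block. The exon and intron part of the design was not run. Depth is unknown, and a missing peak in a double-mutant list may be signal below the caller's threshold. The 678 gained against 2137 lost among stronger peaks cannot decide this. That cutoff itself takes more peaks from the double-mutant lists (61.6% and 63.7% kept) than from the let-418 26 °C lists (93.4% and 95.6% kept).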

Other observations

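The gene families, the noncoding overlaps, the test of genotype at 20 °C, the tests of list length for wild type and for the double mutant, and the arm test for chemoreceptor genes were chosen after the results were seen, and the other tests were set down before their own outcome, on patterns already seen.

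Chemoreceptor-family genes, which encode candidate odorant receptors, lost regions in let-418 at 26 °C against wild type. Of 194 such genes with a region over the gene or within 1000 bp of it, 76 lost one (39.2% against 18% of other genes, odds ratio 2.93, Fisher's exact test across genes, adjusted p = 1.32e-09). The losses covered 73 regions. A gene was counted where a region was held by at least 2 of the 4 libraries, which a lost region meets by itself. A family with few shared regions can therefore show a higher share. The family shares were not set against regions held by 1 library of either group. Chemoreceptor genes cluster on chromosome arms, but among genes of the autosomal arms alone the odds ratio was still 2.03 (adjusted exact p = 8.40e-04). Without wild-type replicate 1, which held the longer wild-type list, the odds ratio was 2.56 over all chromosomes and 1.82 within the arms, and with equal list lengths 2.83 and 1.97. In the double mutant, which carries the same let-418 allele, chemoreceptor and other genes lost regions equally often against wild type (23.6% against 23.6%, odds ratio 1.00). In let-418 at 26 °C against wild type, F-box genes lost regions less often than other genes in the autosomal arms (9.09% against 23%, odds ratio 0.334, adjusted exact p = 1.73e-04). In the double mutant against wild type they did not (28.4% against 23.9%, adjusted exact p = 0.398). With temperature in the let-418 mutant both families gained regions less often than other genes (F-box 2.98% against 14%, adjusted exact p = 8.65e-05, chemoreceptor 5.04% against 13.9%, adjusted p = 0.00681). In the double mutant against let-418 at 26 °C, chemoreceptor genes gained regions in 32% of cases against 21.3% (adjusted exact p = 0.00585) and lost them in 9.39% against 26.5% (adjusted p = 1.15e-06). The gain did not pass within the autosomal arms (odds ratio 1.24, adjusted exact p = 0.392). Chemoreceptor, F-box, BATH and MATH, C-type lectin and nuclear hormone receptor genes pooled did not gain regions in the double mutant more often than other genes (23.1% against 21.4%, p = 0.378, Fisher's exact test), so the arm test of that pool, with an odds ratio of 0.788, decides nothing, a reading settled after its value was seen. The pool joins families that went opposite ways. In the double mutant against wild type, C-type lectin genes gained regions more often than other genes (42.9% against 23.2%, adjusted exact p = 0.00575) and nuclear hormone receptor genes less often (10.3% against 23.5%, adjusted p = 0.0172), and both passed within the autosomal arms (adjusted p = 0.0314 and 0.00585).

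Regions on chromosome X were lost more often than autosomal regions in the double mutant against let-418 at 26 °C. Of 1427 X regions held by both let-418 26 °C libraries, 380 were held by neither double-mutant library (26.6%, interval 24.4 to 29), against 21.8% of autosomal regions. Autosomal regions of the same class, percentile and peak width lost 20.3%, and 0 of 10000 matched draws reached the X share (1.00e-04, the smallest share these draws can give). The excess over matched regions was present at gene ends (27.6% against 22.8%), in gene interiors (29.7% against 17.9%) and beyond genes (22.3% against 17.4%). Among the 3091 regions that all 8 libraries held, the 587 on X had median percentiles of 50.6 and 51.1 in the double-mutant libraries and 54.6 to 57.3 in the other libraries. Against wild type the losses of the double mutant held less of X, 14.1% against 17.9% of the regions held by all 4 libraries (adjusted exact p = 3.77e-04), and the comparison with regions held by 1 library of either group did not pass (adjusted p = 0.519). A lower rank of X chromatin in the double mutant may be a feature of the embryos or of these libraries, which the design does not separate.

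Regions over tRNA genes were rare among some sets of changed regions and not among others. They made up 0.476% of regions lost in let-418 at 26 °C against wild type (9 of 1891, against 2.01% of regions held by all 4 libraries, Fisher's exact test, adjusted p = 4.71e-06) and 0.174% of regions gained in the double mutant against let-418 (adjusted p = 1.75e-09). They made up 2.97% of regions gained in let-418 at 26 °C against wild type (adjusted exact p = 0.0833, and 3.57% against 1.83% with equal list lengths, adjusted p = 0.00153) and 1.86% of regions lost in the double mutant against let-418 (against 2.19%, adjusted p = 0.506). The rarity was not particular to tRNA genes. For snoRNA genes it was 0.106% of those losses against wild type (against 1.94%, adjusted exact p = 4.84e-10) and 0.116% of those double-mutant gains (against 2.06%, adjusted p = 1.75e-09). For snRNA genes it was 0.159% (against 1.12%, adjusted exact p = 7.76e-05) and 0 of 1722 (adjusted p = 1.07e-06). Regions held by 1 library of either group were not used as a reference here. Regions gained with temperature did not hold more tRNA genes than others (odds ratio 1.35, exact p = 0.200), so the value with equal list lengths, an odds ratio of 1.48 (p = 0.104), decides nothing about list length, a reading also settled after its value was seen. Pseudogenes were more frequent among regions gained in the double mutant against let-418 (5.52% against 1.94%, adjusted exact p = 4.84e-10, and 4.05% against 1.85% with equal list lengths). The same held for its gains against wild type (5.01%, adjusted exact p = 4.97e-07) and for losses with temperature (4.64%, 0.0144). In let-418 at 26 °C against wild type it held for losses (4.39% against 1.92%, adjusted exact p = 5.24e-07) and gains (3.06%, 0.0385). The remaining sets did not pass. The widest strong peaks in all libraries included the ribosomal RNA genes on chromosome I, at 15060227 to 15071432 in double-mutant replicate 1.

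The loss of ribosomal protein gene-end regions in the double mutant might come from a lower sensitivity of its lists for peaks of that strength and width. Ribosomal protein regions have narrow peaks (median 220 bp against 280 bp at other gene ends), and other gene-end regions matched on percentile and width in the let-418 26 °C lists were lost in 35.8% of cases, against 25.6% of all others. The observed loss was 50.7% (36 of 71 regions), and 19 of 10000 matched draws were as high (share 0.00200), which argues against sensitivity as the whole cause, although the matched share shows that it can account for part. With the same matching, which looks only for a higher loss, cell cycle (30.3% against 26.0%, share 0.325) and neuron genes (33.3% against 24.9%, 0.199) did not pass, on 33 and 24 regions. Muscle genes, matched in the same way, went the other way (4.35% against 16.9%, on 23 regions). All 8 libraries held 10 ribosomal protein gene-end regions. The median percentile of these 10 was 56.5 and 56.8 in let-418 at 26 °C and 60.7 and 53.6 in wild type. It was 40.4 and 37.4 in let-418 at 20 °C and at most 42.5 in the double mutant. In these 10 regions a lower rank was thus not particular to the double mutant. An effect of the nurf-1 mutation stays open and untested.

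Regions gained in the double mutant against let-418 at 26 °C may be weak peaks near background, since its lists are long and weak. Among the 393 gained regions ranked above the median of both double-mutant lists, 39.7% lay in gene interiors (interval 35.0 to 44.6), against 48.8% of the other gained regions and 973 of the 3875 regions held by all 4 libraries. The regions held by 1 library of either group are a closer reference, chosen after the first value was seen. Of these, 37.2% lay in gene interiors, inside the interval of the stronger gained regions. The bound set beforehand against regions held by all 4 was therefore too easy to pass. The closer reference was not limited to strong peaks. Among peaks of −log10 q of at least 5, 43.7% of the gained regions lay in gene interiors. With the same cutoff, 37.2% of regions held by 1 library of either group did (Fisher's exact test, adjusted p = 0.0222). An excess thus remained at that cutoff, but the share was lower among the stronger gained regions (39.7% against 48.8%). Weak peaks stay open at least as part of the cause. With equal list lengths 43.8% of the gained regions lay in gene interiors, against 24.3% of regions held by all 4. Of those held by 1 library of either group 35.3% did (adjusted exact p = 0.00152), which argues against list length as the whole cause. Also open are a background in the double-mutant libraries with its own distribution along the genome, and a biological difference, which the design does not separate.

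The regions that differ between wild type and let-418 at 26 °C may follow genotype. The let-418 20 °C libraries had no part in choosing them. Of the lost regions, 90.2% were absent from both let-418 20 °C libraries, against 52% of regions that divide the same 4 libraries across groups (odds ratio 8.52, Fisher's exact test, p = 2.06e-113), and 43% of the gained regions were held by both, against 21.1% (odds ratio 2.83, p = 1.75e-26). The dividing regions were each held by 1 let-418 26 °C library, the lost regions by none and the gained regions by both. Any likeness among the let-418 lists, of whatever origin, moves these shares the same way. The values therefore do not separate genotype from another likeness of the libraries. The longer list of wild-type replicate 1 does not account for all of the losses, since with equal list lengths 1420 were lost and the highest mixed pair gave 307. It may account for part, since 1891 were lost with the lists as given. The double-mutant libraries, which carry the same let-418 allele and had no part in the choice either, went with genotype only in part. Of the lost regions 10.3% were held by both of them, against 18.3% of regions that divide the libraries, but 55% were absent from both against 52.1%, and 19.8% of the gained regions were held by both against 18.3%, so following genotype stays a hypothesis from the 20 °C libraries.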
